A study of Mus musculus with 91 samples.

How the data were processed

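Ribosome-associated mRNA of the mouse nucleus accumbens was sequenced in 91 libraries. Per the labels' protocols, tissue of a pair of mice was pooled for each sample, and ribosomes carrying a hemagglutinin tag were pulled down with an antibody from neurons expressing Cre. A Drd1-Cre line marked D1 neurons and an A2a-Cre line marked D2 neurons. Samples were taken at ZT 2, 6, 10, 14, 18 and 22, where ZT counts hours after lights on. The 2 cell types, 2 sexes and 6 times form 24 groups of 3 or 4 libraries, each with a letter from A to E in its title.

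The deposited file holds raw counts per gene, whole numbers that the authors did not normalise. Per the submitters' processing notes, reads were checked with FastQC 0.11.7, and HISAT2 (version not given in the sources used here) and HTSeq 0.10.0 were used. The notes name the builds GRCm38 and GRCh38 without saying what each was used for. The name of the deposited file says that genes were filtered on log CPM; the threshold is not given in the sources used here. The file lists 14355 Ensembl identifiers and pairs none with a gene name. The reference table holds 49997 entries, of which 0 carry an Ensembl identifier, so 0 of the 14355 identifiers could be named. Genes are therefore given by identifier, with at most 2 in each direction per comparison. For the same reason the 32 gene lists fixed before the data were examined could not be scored, marker genes could not be used to check the labels, and checks of GC content and gene length are void.

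Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM normalisation and the quasi-likelihood F-test, with Benjamini-Hochberg adjustment over all 14355 genes and a threshold of 0.05. Each combination of cell type and sex had its own mean and its own cosine and sine term with a period of 24 h. Rhythm was tested on both terms together. The amplitude is the height from mean to peak on the log2 scale, and the peak time comes from the ratio of the terms. 3 fits were made: the D1 libraries, the D2 libraries, and all 91. Sex differences are male minus female and cell type differences are D1 minus D2. CPM values were computed from the deposited counts with TMM-adjusted totals. Adjusted p-values in the text come from edgeR. The model, the alternatives and the rule for identified genes were fixed before the data were examined. That rule took genes of lowest p or largest change among those past the threshold, with a mean of at least 10 CPM for the largest changes; the limit on identifiers then left at most 2 per direction, and none higher in males, where no called gene reached that mean.

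The script was tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes given a rhythm and as many given a change in mean. In the D2 fit over 14355 genes, 28.4% of rhythms with an amplitude of 0.2 on the log2 scale were recovered, 76.1% of those of 0.4 and 98.5% of those of 0.8. In the D1 fit the shares were 32.8%, 82.1% and 98.5%. For a difference in rhythm between D1 and D2 they were 10.4%, 55.2% and 93.9%. False calls made up 4.9% of the calls in the D2 rhythm test, 6.0% in the D1 rhythm test and 7.2% in the D2 sex test. The simulation held no letter effect.

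The pairing of the letters was checked from the correlation of deviations from group means. In D2 libraries, all of the 243 same-letter pairs exceeded 0.1 (100%), with a median of 0.72 and a lowest value of 0.19. The letters were therefore treated as pairing D2 libraries, and values with the letter as a block are given beside D2 results where they change a call or move a count by over 1.5 times. In D1 libraries 66.8% of 223 pairs exceeded 0.1 and the lowest was -0.61, so letters were not treated as pairing there. Within groups no library was a copy of another: the lowest mean chi-square per gene among the 129 pairs of libraries of the same group was 4.24, where 1 would be sampling noise. Pairs across groups were not compared.

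Alternatives were DESeq2 1.42.0, limma 3.58.1 voom with quality weights, RLE size factors, filterByExpr, a letter block, each letter left out, a least squares cosinor on log2(CPM + 1), time as a factor of 6 levels, depth as a covariate, other choices of libraries, and a single rhythm for both sexes. Leaving out 3 D1 libraries that stand apart, with and without the block, and a block within cell type were added after the data were seen. To ask how often other groupings give as many genes, labels of time or sex were shuffled in 100 splits for each cell type, and labels of cell type in 40 splits of all libraries. The number for the unblocked cell type fits was first 40; it was raised to 100 after those first 40 had been examined, and the first 40 are part of the 100. For rhythms in D2 neurons and for the sex difference in mean level in D1 neurons this moved the share from the limit of 0.05 to below it, and both counts are given there. The labels' protocols do not say that libraries of a group share animals, and p-values of the tests of single genes measure the spread between pooled samples. Those of Fisher's exact test do not.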

Results

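Gene expression in D1 and D2 neurons of the nucleus accumbens was measured by sequencing ribosome-bound mRNA over the day in both sexes. D1 and D2 neurons are the principal projection neurons of this region, named for the dopamine receptor they carry. The D1 libraries numbered 23 from females and 22 from males, and the D2 libraries 23 from each sex. Total counts ranged from 6872165 to 24665262 per library (14296688 ± 3740182, SD, n = 91). The 10 most abundant genes took 5.84% to 12.47% of the counts of a library. Genes are given by Ensembl identifier, because the deposited file does not pair them with names.

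The first principal component held 41.3% of the variance, and the replicate letter accounted for 60.9% of it, the time of day for 0.9%. In D2 neurons libraries of letters A and B deviated from their group means in similar ways, as did those of C and D. The median correlation of these deviations was -0.77 between A and C. Deviations cancel out within a group, which lowers values between letters. D2 libraries of letter A held 19727033 ± 3011572 counts (SD, n = 12), and those of letter D 10904585 ± 1753165 counts (SD, n = 12). 3 libraries of D1 neurons from males stood apart (ZT10 B, ZT22 B and ZT18 D), with 789, 722 and 205 genes at 0.

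**Figure D1:**
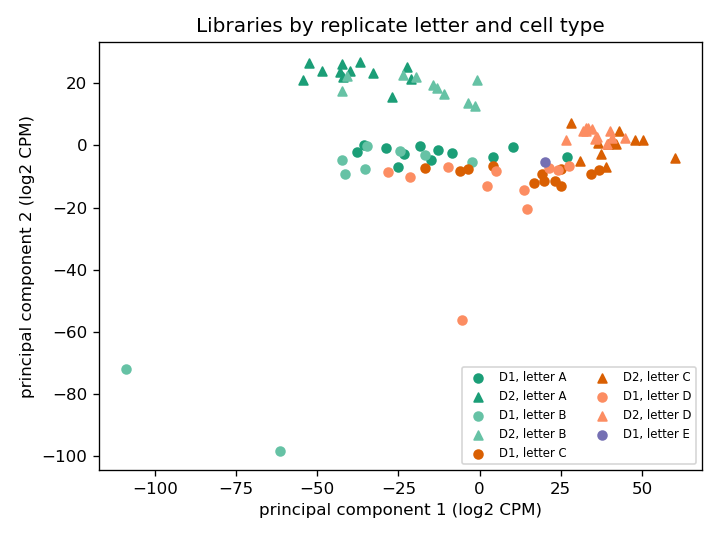
Principal components 1 and 2 of log2 CPM for the 91 libraries, with circles for D1 neurons, triangles for D2 neurons and a colour for each replicate letter. Component 1 holds 41.3% of the variance and parts letters A and B from C and D among the D2 libraries, while D1 libraries of these letters overlap and 3 of them lie far below the rest.

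Which genes follow a daily rhythm was asked in each cell type. In D2 neurons 422 of 14355 genes were rhythmic, with a median amplitude of 0.17 on the log2 scale. ENSMUSG00000055866 rose from 57.8 ± 6.09 CPM at ZT6 (SD, n = 7) to 103.8 ± 15.9 CPM at ZT14 (SD, n = 8), with an amplitude of 0.43 ± 0.04 (SE), a fitted peak at ZT 15 and an adjusted p of 1.78e-09. ENSMUSG00000038550 rose from 8.13 ± 0.934 CPM at ZT22 (SD, n = 8) to 16.0 ± 2.81 CPM at ZT10 (SD, n = 8), with a peak at ZT 11 and an adjusted p of 5.36e-09. Peaks gathered at opposite times, with 142 genes between ZT 4 and 8 and 144 between ZT 16 and 20. Over all genes, with the letter as a block, a single axis through ZT 5.1 held 68.1% of the rhythm variance. The opposite groups were therefore not shown to be separate rhythms. With the letter as a block, 3198 genes were rhythmic, again most often between ZT 4 and 8 (985) and ZT 16 and 20 (987). Without letter C the count without the block was 55. Shuffled time labels gave as many as 422 genes in 4 of 100 splits, the real one included, so chance is not excluded for the unblocked count. Shuffled within letter and sex, no other split gave as many as 3198.

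In D1 neurons 71 genes were rhythmic, with a median amplitude of 0.31. ENSMUSG00000055866 went from 54.5 ± 3.78 CPM at ZT6 (SD, n = 8) to 94.2 ± 7.70 CPM at ZT14 (SD, n = 7), with an amplitude of 0.37 ± 0.04 (SE) and an adjusted p of 3.94e-07. ENSMUSG00000038550 went from 7.33 ± 0.995 CPM at ZT22 (SD, n = 8) to 15.9 ± 2.67 CPM at ZT10 (SD, n = 8), with an amplitude of 0.55 ± 0.05 (SE) and an adjusted p of 9.06e-09. The peaks of 29 genes fell in the light phase and of 42 in the dark phase, with 25 between ZT 16 and 20. Without the 3 libraries that stand apart the count was 177, and without letter C it was 13.

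**Figure D2:**
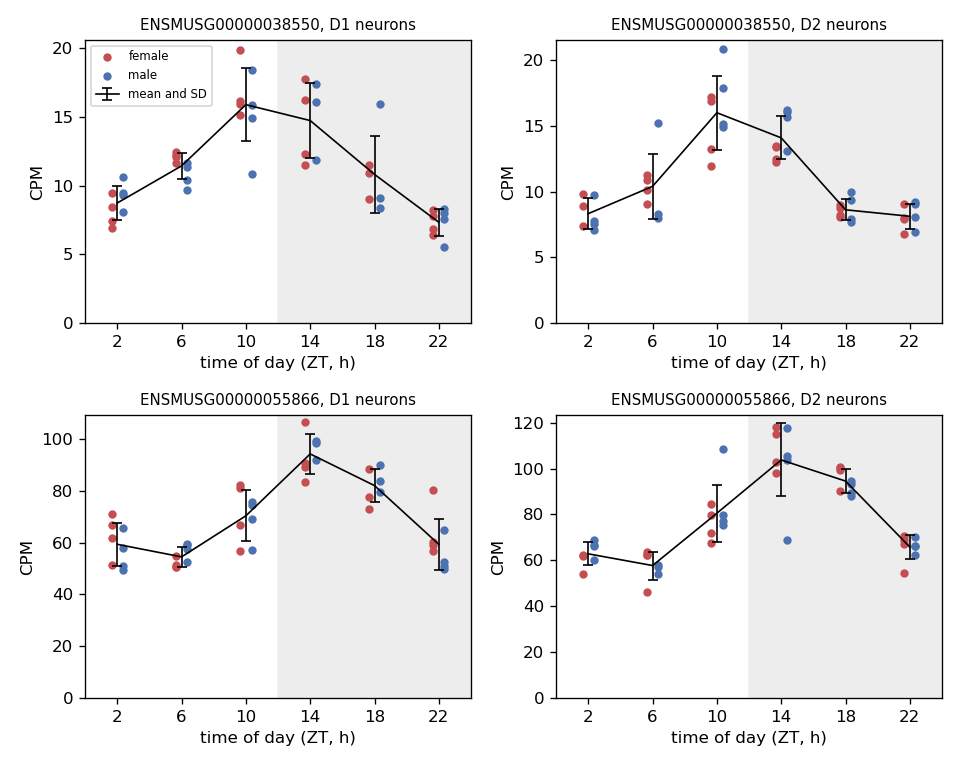
CPM of ENSMUSG00000038550 (top) and ENSMUSG00000055866 (bottom) against time of day in D1 (left) and D2 (right) neurons, with points for libraries, red for females, blue for males, and black lines for the mean and SD over both sexes. Grey marks the dark phase, and the first gene is highest at ZT10 and the second at ZT14 in both cell types.

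**Figure D3:**
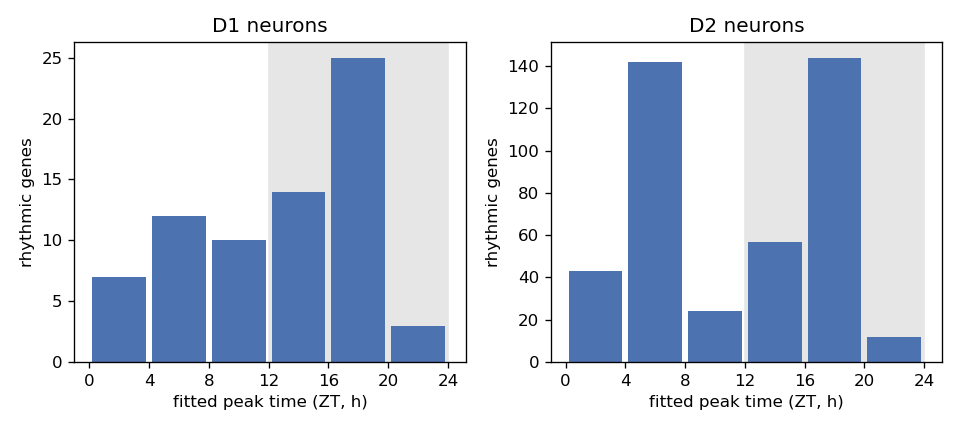
Number of rhythmic genes by fitted peak time in 4-h bins for D1 (left, 71 genes) and D2 (right, 422 genes) neurons, with the dark phase in grey. The D2 counts are highest in the bins from ZT 4 to 8 (142) and ZT 16 to 20 (144).

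Both cell types shared 32 rhythmic genes, where 2.1 would be expected of independent lists (Fisher's exact test, one-sided, p = 1.67e-30). The test takes genes as independent, but genes move together, so its p-value does not measure the spread between samples. Peak times of 31 of the 32 genes lay within 3 h, with a median difference of 0.74 h. With the letter as a block 107 genes were shared, where 36.1 would be expected, and the peaks of 92 lay within 3 h. Across all genes, which are not independent replicates, the fitted rhythms of D1 and D2 neurons correlated with r = 0.03 (permutation p = 0.93, two-sided). A test of the difference in rhythm passed for 2 genes, ENSMUSG00000064945 (adjusted p = 0.0128) and ENSMUSG00000088088 (adjusted p = 0.0198). ENSMUSG00000064945 reached 60.9 ± 80.4 CPM in D1 neurons at ZT10 (SD, n = 8), where 1 library (male, letter B) held 242 CPM. Neither gene passed without the 3 libraries that stand apart (adjusted p = 0.122 for each), where 1 other gene did, nor without letter B, C or D. The amplitude of the difference was 1.80 for ENSMUSG00000064945 and 0.79 for ENSMUSG00000088088 with all libraries, and 1.33 and 0.62 without those 3. Without letters B, C and D in turn it was 1.37, 1.69 and 1.76 for the first gene and 0.67, 0.84 and 0.71 for the second. With the letter as a block 76 genes passed, and with the letter as a block within each cell type 465 did, these 2 among them each time. Both also passed with the block and without the 3 libraries (adjusted p = 0.0146 for each).

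Rhythms were then tested in each sex. In D2 neurons 34 genes were rhythmic in males and 71 in females. Both sexes shared 14, where 0.2 would be expected (Fisher's exact test, one-sided, p = 1.73e-24). That test, too, takes genes as independent. With the letter as a block the counts were 1308 and 1799, with 533 in both (163.9 expected), of which 340 peaked within 3 h. In D1 neurons 6 genes were rhythmic in males and 4 in females, with 2 in both. No gene passed the edgeR test of a difference in rhythm between the sexes in D1 neurons, where 226 had an unadjusted p under 0.05, nor in D2 neurons, where 389 did; chance alone would give 718. DESeq2 gave 0 in D1 and 2 in D2 neurons, and limma voom with quality weights gave 2885 in D1 and 3 in D2 neurons. The block gave 3 genes in D2 neurons, and sex labels shuffled within letter gave as many in 7 of 100 splits. Across genes, the rhythms of males and females correlated with r = 0.35 in D2 neurons (permutation p = 0.001, the smallest that 1000 permutations can give). With the letter as a block and time shuffled within letter, r was 0.32 in D2 neurons (permutation p = 0.02). In D1 neurons r was 0.25 without the block (permutation p = 0.22).

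D1 and D2 neurons differed in the mean level of 2770 genes, 1355 higher in D1 and 1415 higher in D2. ENSMUSG00000027400 was at 286.3 ± 74.7 CPM in D1 (SD, n = 45) and 38.9 ± 6.90 CPM in D2 neurons (SD, n = 46), 7.24-fold higher (adjusted p = 3.16e-53). ENSMUSG00000050473 was 4.26-fold higher in D1 neurons (adjusted p = 2.53e-47). In the other direction, ENSMUSG00000052305 was at 0.806 ± 0.470 CPM in D1 (SD, n = 45) and 38.9 ± 21.5 CPM in D2 neurons (SD, n = 46; adjusted p = 2.57e-42). ENSMUSG00000073940 was at 0.501 ± 1.09 CPM in D1 and 25.5 ± 21.9 CPM in D2 neurons (adjusted p = 2.36e-30). Single D2 libraries ranged from 11.7 to 105.9 CPM for ENSMUSG00000052305 and from 4.12 to 92.1 CPM for ENSMUSG00000073940. Differences of over 2-fold were found for 31 genes higher in D1 and 188 higher in D2. The cell types come from different mouse lines, so the line and the cell type cannot be told apart. Marker genes could not be used, so RNA in the pull-down from cells other than the labelled neurons was not tested. With the letter as a block 5471 genes differed and the share higher in D1 neurons was 59.6%, against 48.9% without it; with depth as a covariate it was 59.5% of 4400, and without letter D 41.6% of 1767.

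The number of genes whose mean level differed between the sexes depended on the letters. In D2 neurons 31 genes differed, 1 higher in males and 30 in females, and with the letter as a block 1357 did, 719 higher in males and 638 in females. In D1 neurons 6 genes differed, 1 higher in males and 5 higher in females, and without letter B 294 did, 232 of them higher in males. ENSMUSG00000086503 was at 4868 ± 1531 CPM in D1 neurons of females (SD, n = 23) and 19.9 ± 34.7 CPM in those of males (SD, n = 22; adjusted p = 7.8e-16), and at 5474 ± 1028 and 42.4 ± 70.0 CPM in D2 neurons (SD, n = 23 each; adjusted p = 1.9e-15). Every female library was above every male library. ENSMUSG00000037369 was at 104.5 ± 16.7 CPM in D1 neurons of females (SD, n = 23) and 70.0 ± 7.08 CPM in those of males (SD, n = 22; adjusted p = 2.4e-08). The gene higher in males was ENSMUSG00000001435 in both cell types, identified after its values were seen because its mean of 3.36 CPM lies below the limit for naming. It differed by 0.90 ± 0.15 (SE) on the log2 scale in D1 (adjusted p = 0.00232) and by 0.42 ± 0.09 (SE) in D2 neurons (adjusted p = 0.0253). Its call was lost in D1 neurons with DESeq2 and without letter C or D, where no gene was called higher in males. The same held in D2 neurons without letter A, C or D. ENSMUSG00000077394 differed by -0.54 on the log2 scale in D2 neurons, higher in females (adjusted p = 0.0217), and by -0.50 with the letter as a block (adjusted p = 4.45e-06). Without letter B or C the difference was -0.52 and -0.53 and did not pass (adjusted p = 0.361 and 0.802). For no gene did the sex difference itself differ between the cell types in edgeR, where 908 had an unadjusted p under 0.05. DESeq2 gave 21 such genes and the block 1. Of the 31 genes called in D2 neurons, 18 differed in the same direction in D1 neurons. All 6 called in D1 neurons did so in D2 neurons, and 4 genes were called in both. The test therefore does not show that the sex differences of D2 neurons hold in D1 neurons.

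**Figure D4:**
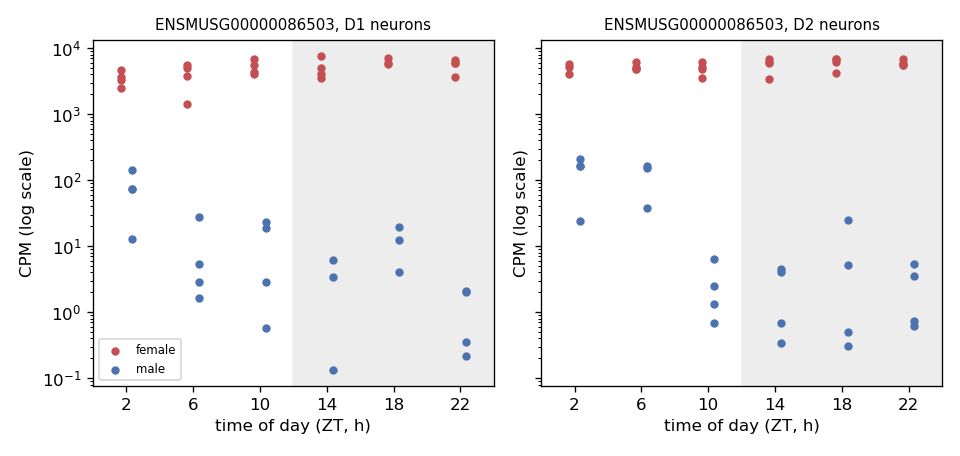
CPM of ENSMUSG00000086503 on a log scale against time of day in D1 (left) and D2 (right) neurons, with points for libraries, red for females and blue for males, and the dark phase in grey. All female libraries lie above all male libraries, and male libraries reach 207.3 CPM at ZT2.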

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

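What the splits within letter would show for rhythm in D2 and for sex in D1 neurons was written down before those results were seen; the other tests below were chosen after. 62 groups of 4 to 10 samples were tested for a sample far from the others, and 11 had one. Some groups were CPM values at the highest and lowest times of genes already picked, so no chance rate is given. The median log2 difference of a library to its own set stood out for D1 female ZT22 B (0.464), D1 male ZT10 B (1.39), D1 male ZT22 B (1.38), D2 female ZT10 A (0.716) and D2 female ZT14 A (0.812). CPM values far from the rest were 47.0 of ENSMUSG00000045193 and 242 of ENSMUSG00000064945 in D1 male ZT10 B, 8.92 of ENSMUSG00000033327 in D2 female ZT10 B and 69.0 of ENSMUSG00000055866 in D2 male ZT14 A. Others were 104 of ENSMUSG00000021775 in D2 male ZT2 B and 26.7 of ENSMUSG00000064945 in D2 female ZT2 D. Rhythms that differed between D1 and D2 had a difference of amplitude 1.8 for ENSMUSG00000064945 and 0.79 for ENSMUSG00000088088.

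The count of rhythmic genes in D2 neurons went from 422 to 3198 with the letter as a block. Time labels shuffled without regard to letter gave as many as 422 genes in 4 of 100 splits, the real one included, and the highest other split gave 10200. In the first 40 splits it was 2, a share at the limit of 0.05. A share this close to the limit cannot exclude chance for the unblocked count. A split that calls so many genes points to a structure of the samples. Shuffled within letter and sex, 1 of 100 splits gave as many as 3198, the real one, and the highest other gave 11. Across genes the main rhythm axis correlated with the axis between letters by -0.01. The splits within letter argue against letters as the source of the blocked count. The correlation cannot decide this, because the letter block had already been removed from the rhythms it used. The numbers in the sample titles rise with the time of day within each cell type and sex, and what they stand for is not given. A processing order that followed the time of day was not tested. Splits within letter cannot tell it apart from time, so it stays open for that count.

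The sex difference in D1 neurons went from 6 to 1042 genes with the block. 1 of 100 splits within letter and time gave as many as 1042, the real one, but the highest other gave 955, which points to a structure that the letters do not describe. Without the 3 libraries that stand apart the blocked count was 33. These libraries may therefore account for most of the blocked count. Across genes the letter axis correlated with the sex difference by -0.52 in D1 and -0.54 in D2 neurons, so sex differences lay partly along the axis between letters in both cell types, which bears on the blocked sex count of 1357 in D2 neurons as well.

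ENSMUSG00000086503 averaged 107.8 CPM in the male libraries at ZT2, 2.085% of the female mean, 55.9 CPM at ZT6 and 1.86 CPM at ZT22. A permutation test over the 6 times gave p = 1e-05, the smallest that 100000 permutations can give. ZT2 was above the median of the other times in 8 of 8 combinations of letter and cell type, against differences between letters. RNA or reads from female libraries could give such a level, but the other 29 genes higher in females in D2 neurons would then shift by only 0.0061 on the log2 scale in the D2 male libraries at ZT2, against 0.02 ± 0.03 (SE) seen. D1 libraries were not tested in this way. That explanation cannot be told apart from a daily change in males, because the shift lies below the spread.

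Splits gave as many rhythmic genes in D1 neurons in 1 of 100, the real one (71 real, highest other 1). In D1 neurons of females it was also 1 of 100 (4 real, highest other 0). Both argue against chance, but the shares here are not adjusted for the number of split tests. For D1 neurons of males 8 of 100 gave as many (6 real, highest other 2271), so chance is not excluded. For D2 neurons of females 5 of 100 did (71 real, highest other 8583), so chance is not excluded for the count without the block. Shuffled within letter, 1 of 100 did (1799 real, highest other 97), which argues against chance for the blocked count. For D2 neurons of males it was 4 of 100 (34 real, highest other 10449), and within letter 1 of 100 (1308 real, highest other 1). For mean levels, 1 of 40 did between cell types (2770 real, highest other 0), 2 of 100 between sexes in D1 (6 real, highest other 1077) and 1 of 100 in D2 neurons (31 real, highest other 0). For the sex difference in D1 neurons the first 40 splits also held 2, a share at the limit. The number was raised after those had been seen, so chance is not excluded there. Within letter and time, 1 of 100 gave as many sex differences in D2 neurons (1357 real, highest other 4). For the rhythm difference between cell types 2 of 40 did (2 real, highest other 3815), so chance is not excluded for the count without the block. The counts of 76 with the block and 465 with the block within cell type were not set against other splits. The counts of 0 could not be tested in this way, because every split gives at least 0 genes. All 100 of 100 splits therefore matched for rhythm between sexes in D1 (highest other 5) and in D2 (highest other 6804). So did 40 of 40 for the sex difference between cell types (highest other 0).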

How the results depend on the processing

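Alternatives were fixed before the data were examined, except leaving out the 3 libraries that stand apart and the block within cell type, which were chosen after. Of 236 alternative values for 18 results of identified genes, 222 kept direction and side of the threshold, 12 lost the threshold and 0 reversed. The remaining adjusted p-values were not given by DESeq2. Time as 6 levels is left out of the 236 values, and under it neither gene whose rhythm differed between D1 and D2 passed. ENSMUSG00000001435, identified later, is also left out. The counts moved more, and the cause was not tested. RLE size factors and filterByExpr (which removed 3 genes in D1 and 0 elsewhere) moved no count by over 1.5 times. The gene list scores and tests, with their alternatives, were not run, because identifiers could not be named. Rhythms of small amplitude were recovered least in the simulated counts; recovery by count level was not tested.

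For rhythm in D1, D2, D1 males, D1 females, D2 males and D2 females in turn, DESeq2 gave 215, 669, 41, 8, 144 and 261 genes, and voom with quality weights 717, 3046, 89, 2524, 4357 and 209. Depth as a covariate gave 314, 1076, 51, 136 and 346 in all of these but D1 females. The replicate block gave 162, 3198, 19, 1308 and 1799, again without D1 females, and least squares 56 in D2 males and 133 in D2 females. Time as 6 levels gave 26 in D1, 91 in D2, 7 in D2 males and 15 in D2 females. All 91 libraries gave 102 in D1 males and 15 in D2 males, and only that set of libraries gave 1, 9, 12 and 16 in D1 males, D1 females, D2 males and D2 females. For the rhythm difference between sexes, voom gave 2885 in D1 and 3 in D2, DESeq2 2, the replicate block 3 and time as 6 levels 1 in D2. For that between cell types, DESeq2 gave 32, voom 2266, depth 63, time as 6 levels 0, the replicate block 76 and the block within cell type 465.

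For mean levels between cell types, depth gave 4400, voom 8248 and the replicate block 5471. Between sexes, depth gave 13 in D1, voom 15 in D1 and 48 in D2, and the replicate block 1042 in D1 (774 higher in males) and 1357 in D2. The sex difference between cell types gave 21 with DESeq2, 1 with the replicate block and 1 with the block within cell type. In D1 libraries same-letter pairs correlated by a median of 0.20, so the letters are not taken to pair them. Without the 3 libraries that stand apart, the counts were 177 for D1 rhythm, 14 in males, 7 in females and 1 for the difference between cell types. Leaving them out with the replicate block gave 293, 19, 28 and 30, 6057 genes between cell types and 33 between sexes in D1. At an unadjusted p under 0.01 the overlaps were 134 genes between cell types, 39 between sexes in D1 and 151 in D2.

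Without each replicate letter in turn, rhythm counts ranged from 13 to 54 in D1, 55 to 261 in D2, 0 to 8 in D1 males, 1 to 4 in D1 females, 3 to 26 in D2 males and 7 to 20 in D2 females. They ranged from 0 to 1 for the sex difference in rhythm in D2, and from 0 to 7 for the cell type difference. Mean level counts ranged from 1767 to 6912 between cell types, 2 to 294 between sexes in D1, 7 to 28 in D2 and 0 to 1 for the sex difference between cell types. The highest D1 sex count, 294 (232 higher in males), came without letter B, and the highest cell type count, 6912, without letter A.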

Other observations

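The peak times found in part of the libraries were compared with those in a left-out letter, a comparison chosen after the data were seen. Peaks gather at a few times and genes move together, so no chance level is given for it. In D2 neurons, for letters A, B, C and D in turn, 85.4%, 92.5%, 98.2% and 83.6% of the genes called without that letter peaked within 3 h in it, and with the letter as a block 66.9%, 76.1%, 86.3% and 57.7%. In D1 neurons the shares were 90.9% of 22 genes, 64.8% of 54, 100% of 13 and 100% of 18. Sex differences were also compared between letters, across genes, which are not independent replicates. Their Spearman coefficients ranged from -0.03 (B and C) to 0.63 (A and C) in D1 neurons and from 0.10 (A and D) to 0.45 (B and C) in D2 neurons. In D2 neurons the main axis of rhythm ran through ZT 5.1 and held 68.1% of the rhythm variance.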
